A study of Mus musculus with 6 samples.

How the data were processed

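Total RNA of mouse embryonic stem cells and embryoid bodies was profiled on single-colour (Cy3) Agilent miRNA arrays, with 2 arrays for each of 3 groups. The labels describe extraction with Trizol and a Cy3 labelling kit for amplified cRNA from total RNA, a protocol usual for messenger RNA. Which labelling was used for these miRNA arrays is not settled here. Per the file headers, each deposited scanner file holds a total gene signal (an intensity per miRNA), its error and a detection flag for 1268 features, of which 21 are controls and 1247 are mouse miRNAs. Undetected miRNAs are deposited with an intensity of 0.1. Scanner software, its version, and the rule behind the detection flag are not given in the sources used here. File names place all arrays on a single slide, with the mESC arrays in another row of it than the EB arrays, so that row and cell state cannot be told apart.

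A table of the whole series was deposited by the authors with raw, normalized and control columns. Its raw intensity columns equal the scanner files for all 1253 shared rows. Its normalized values are a ratio deposited by the authors: the array's signal divided by a control value per miRNA, found from the values to be the median over the table's 8 arrays with a minimum of 10, with no scaling between arrays. Medians of this ratio over the 484 tested miRNAs were 0.724 and 0.766 for mESCs, 1.23 and 1.32 for normoxic EBs, and 1.19 and 0.990 for hypoxic EBs. The table has 6 further columns for 2 arrays that match no sample in the list, and these were not used here. It also gives positions that mix genome builds without naming one, so no coordinates are printed. Chromosomes and host genes come from RefSeq gene tables of GRCm38.p6 by name, where 450 of 484 tested miRNAs matched.

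Each array was scaled to the 75th percentile over the 391 miRNAs detected on all arrays, multiplied back by the mean of these percentiles, floored at 2.91 (the highest, over the arrays, of the lowest scaled signal of a detected miRNA), and put on the log2 scale. The 484 miRNAs detected on both arrays of at least 1 group were tested. Group means of all 6 arrays were fitted with limma 3.58.1 (lmFit and eBayes, residual df 3, prior df 1.43) in R 4.3.3, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Every adjusted p of a single miRNA is from that limma fit. A miRNA detected on both arrays of a group and neither of the other enters the fit at the floor, so its fold depends on the floor. The lowest detected signal is no limit for it either, since some miRNAs undetected on an array read above the floor on its replicate. Its detection and adjusted p are therefore given without a fold. The adjusted p depends on the floor as well, since arrays set to the floor share a single value and have no measured spread. List medians and interval widths that include such members depend on the floor too. Figures were drawn with Python 3.11.15.

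There were 16 lists of miRNAs, fixed with the other choices before the data were examined: the miR-290 to miR-295, miR-302/miR-367, miR-17/92, Dlk1-Dio3 and Sfmbt2 clusters, the let-7, miR-200 and miR-34 families, muscle, smooth muscle and endothelial, hypoxia-associated, fibroblast, neural, endoderm and blood-cell miRNAs, and entries derived from rRNA or tRNA. The 13 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01. With a correlation estimated per list 0 lists passed camera in any comparison, while 1, 1 and 1 had an unadjusted p under 0.05 and 11, 7 and 11 passed fry. Adjusted p-values of lists are over the lists tested.

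Named miRNAs followed a rule: per comparison, the 6 largest rises and 6 largest falls past the threshold with arrays not overlapping and detection on both arrays of both groups, the 4 largest rises and falls, by the ratio to the lowest detected signals of the other group, among those detected on both arrays of one group and neither of the other, up to 4 members per list past the threshold by size, and 8 fixed miRNAs (miR-210-3p, miR-294-3p, miR-295-3p, miR-302b-3p, miR-1a-3p, miR-133a-3p, miR-206-3p and miR-21a-5p). Only part of those it selects is printed. Members of genomic clusters outside the lists were chosen after their values were seen.

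The fit was tested on simulated data built on the comparison of normoxic EBs with mESCs, with 484 miRNAs in 20 simulations. It called 38.6% of miRNAs changed 1.2-fold, 83.5% of those changed 1.5-fold and 95% of those changed 2-fold, and 3.82% of calls were unchanged miRNAs. A list lowered 2-fold was called in 100% of simulations. The noise was drawn independently for each miRNA and array, so these rates do not cover miRNAs that vary together. The estimated correlation within the miR-302/miR-367 list was 0.58.

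Alternatives fixed in advance were other scalings (75th percentile of all mouse miRNAs, median, quantile, none, the authors' normalized ratio), floors 4 times as high and at 0.5 of the height, other filters on dim miRNAs, eBayes with trend and robust settings, only the 4 arrays compared, the replicate number as a block, leaving out each array (the lone array of its group is then assumed to vary like the other groups), a rule of at least 2-fold without overlap, and other list tests (an estimated correlation, and fry). Scaling to the 5 hur control features and cyclic loess were added after the data had been seen. Probes named hur are positive control features of the array design, whose nature is not given in the sources used here.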

Results

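MicroRNA levels were measured in mouse embryonic stem cells (mESCs) of a C57 line and in embryoid bodies (EBs), the aggregates that such cells form when they start to differentiate. The mESCs grew on mitomycin C-treated embryonic fibroblast feeders with leukaemia inhibitory factor (LIF), a cytokine that holds them undifferentiated. The EBs were made in hanging drops without LIF or feeders. Both were kept for 16 h, the mESCs under normoxia and the EBs under normoxia or hypoxia, and the series title places the work in the context of myogenic differentiation. Each of the 3 conditions was hybridised to 2 single-colour Agilent arrays carrying 1247 mouse miRNAs. The scanner called 408 and 415 miRNAs detected on the mESC arrays, 446 and 473 on the normoxic EB arrays, and 495 and 471 on the hypoxic EB arrays. The 75th percentile of the 391 miRNAs detected on all 6 arrays was 137 and 140.0 units on the mESC arrays, 222 and 237 on the normoxic EB arrays, and 219 and 175 on the hypoxic EB arrays. Detection was flagged before scaling, so a dim miRNA could go undetected on the mESC arrays through their lower brightness alone. Arrays of a group correlated across miRNAs with r = 0.997 in each of the 3 pairs. Their scaled differences had an SD of 0.609 to 0.876 times the scanner's own error, so each pair differed by less than that error. Nothing in the labels says that the arrays came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision. For a miRNA set to the floor in a group, that group adds no measured spread, and its p-value depends on the floor. Values below are scaled signals, given as mean ± SD with n = 2, and folds carry 95% intervals from the limma fit.

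The first comparison asked which miRNAs differed once mESCs had been moved into embryoid bodies, both under normoxia. The miR-302/miR-367 cluster, encoded within the Larp7 gene on chromosome 3 and characteristic of pluripotent cells, fell in normoxic EBs in all 7 tested members (7 with p adjusted over the list alone). miR-302d-3p went from 1356 ± 22.9 to 382 ± 25.5, which was 3.55-fold lower (3.16 to 3.99, adjusted p = 0.000348). miR-367-3p was 3.20-fold lower (2.81 to 3.66) and miR-302b-3p 2.96-fold lower (2.57 to 3.41). The list test put the cluster below the other miRNAs (camera, adjusted p = 7.77e-05; adjusted p = 0.273 with an estimated correlation). Of the large repeat cluster in an intron of Sfmbt2, 42 of whose 49 tested members have a hairpin within that gene on chromosome 2, 44 members fell and 0 rose (44 over the list alone), with a median log2 change of -0.71. miR-669e-3p was 3.84-fold lower (2.27 to 6.51), and miR-669l-3p was detected on both mESC arrays and neither normoxic EB array (adjusted p = 0.0166). This list also passed (adjusted p = 9.6e-17; adjusted p = 0.136 with an estimated correlation). Without scaling its median was -0.01 and 3 members fell.

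The miR-290 to miR-295 cluster, the most abundant early embryonic family of mouse ES cells, had a median log2 change of -0.22, which turned to 0.51 without scaling. miR-294-3p stood at 7985 ± 279 in mESCs and 6823 ± 577 in normoxic EBs (adjusted p = 0.0651), and miR-295-3p at 8337 ± 344 and 7779 ± 600.5 (adjusted p = 0.293). Of 14 members 4 fell and 0 rose (4 over the list alone), whereas 9 rose without scaling. The fallers included miR-291a-5p at a log2 change of -0.57 and miR-290-3p at -0.52. The list passed (adjusted p = 0.0224; adjusted p = 0.422 with an estimated correlation), but not with quantile normalization, without scaling or with a floor 4 times as high. A difference between both clusters within an array is unchanged by any scaling that multiplies the whole array by a single factor. Quantile normalization and cyclic loess can change it. Within each array, the mean log2 signal of miR-302/miR-367 minus that of miR-290 to miR-295 was -0.01 and -0.07 in mESCs, -1.17 and -1.24 in normoxic EBs, and -1.41 and -1.62 in hypoxic EBs. These means take in bright and dim arms alike, so the level of the difference does not compare the abundance of the clusters. With 2 arrays per group an exact two-sided permutation test cannot give a p below 0.333.

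**Figure D1:**
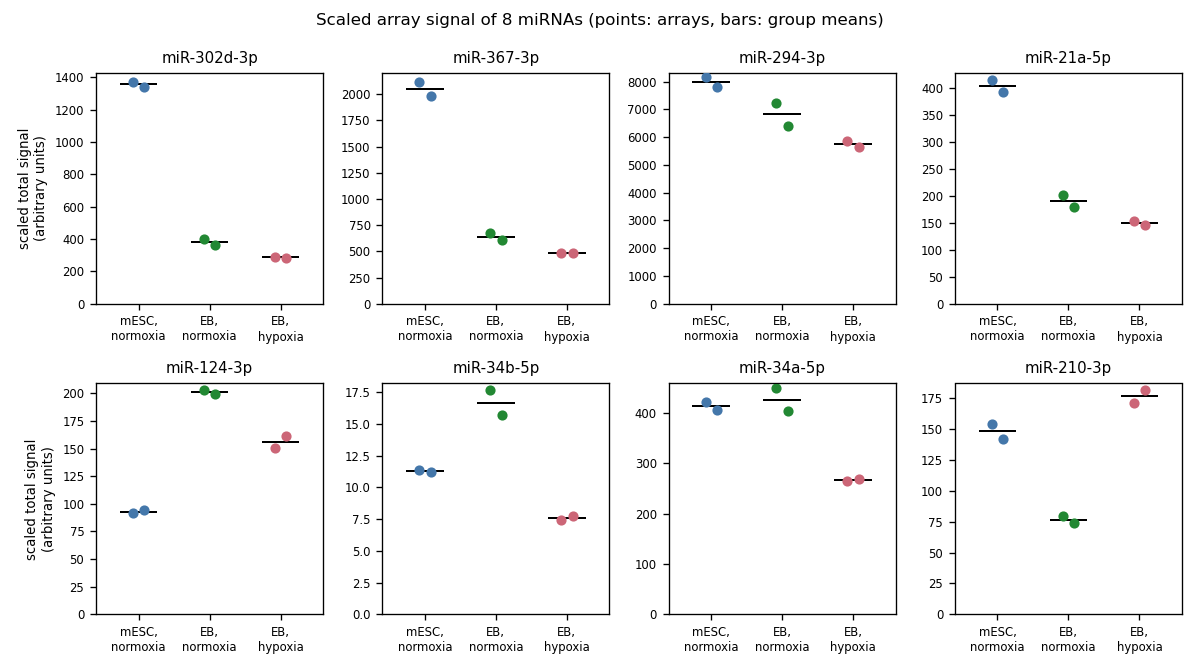
Scaled total signal (arbitrary units, vertical axes from 0) of 8 miRNAs on the 2 arrays of each group, with points for arrays and bars for group means. miR-302d-3p drops from 1356 in mESCs to 382 in normoxic EBs, whereas miR-294-3p goes from 7985 to 6823, a difference that turns upward without scaling, and miR-210-3p reads 148, 76.5 and 176 in the 3 groups.

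Some miRNAs of differentiated cell types were higher in the normoxic EBs and others were lower. Of 8 tested neural miRNAs 2 rose and 3 fell (2 and 3 over the list alone). The neuron-enriched miR-124-3p went from 92.7 ± 1.92 to 201 ± 2.96, 2.17-fold higher (1.96 to 2.40, adjusted p = 0.000466), and its other arm, miR-124-5p, was detected on both normoxic EB arrays and neither mESC array (adjusted p = 0.000348). miR-9-3p fell with a log2 change of -0.71, which turned to 0.02 without scaling, and miR-218-5p, also lower (adjusted p = 0.0203), was detected on 1 of the 2 normoxic EB arrays. The neural list did not pass (adjusted p = 0.831). Of 4 blood-cell miRNAs 3 rose (3 over the list alone): miR-150-5p 2.74-fold (2.46 to 3.05), miR-142-3p 2.08-fold (1.86 to 2.33) and miR-142-5p (adjusted p = 0.00554). The last was detected on 1 of the 2 mESC arrays, so the size of its change depends on the floor. The adjusted p of this list was 0.0664. In the miR-34 family, transcriptional targets of p53, 3 of 4 members rose (3 over the list alone), with miR-34b-5p up by 0.56 in log2 and miR-34a-3p and miR-34c-5p detected on neither mESC array (list adjusted p = 0.0664). The remaining member, miR-34a-5p, by far the brightest, had a log2 change of 0.04 (adjusted p = 0.657). miR-125b-5p rose 2.75-fold (2.32 to 3.25). The let-7 family, low in ES cells, was dim throughout: 2 of 6 tested members rose and 1 fell (2 and 1 over the list alone), and the median turned from -0.04 to 0.28 without scaling. let-7f-5p was detected on both normoxic EB arrays and neither mESC array (adjusted p = 0.0011) and let-7b-5p went from 7.79 ± 0.342 to 4.11 ± 0.457, while the list as a whole did not pass (adjusted p = 0.949) and its mean was 0.04, above 0 like the direction of the test.

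Muscle miRNAs were almost absent from the arrays. miR-1a-3p and miR-133a-3p were detected on no array, and miR-206-3p on 1 mESC array and 1 hypoxic EB array. Of 18 muscle miRNAs 1 could be tested, miR-208a-5p, whose gene lies in a cardiac myosin gene, and it rose 1.98-fold in normoxic EBs (1.69 to 2.32). The other arm of that hairpin, miR-208a-3p, was detected on no array, so a rise of the cardiac miRNA is not shown. The endothelial miR-126-3p fell by 0.35 in log2, a direction that turned to 0.38 without scaling, and it was the only tested member of the 7 smooth muscle and endothelial miRNAs. None of 11 endoderm miRNAs could be tested.

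Of 13 tested fibroblast miRNAs, listed because of the feeders, 7 fell and 3 rose (8 and 3 over the list alone), and the median turned from -0.42 to 0.28 without scaling. miR-21a-5p, abundant in many adherent cells, was 2.13-fold lower in EBs (1.84 to 2.45; not past the threshold without scaling), while miR-125b-5p and miR-199a-3p rose, the latter detected on neither mESC array. The list did not pass (adjusted p = 0.076). The miR-200 family of epithelial cells had 4 of 6 members lower (4 over the list alone, list adjusted p = 0.0664), a direction that also turned without scaling (median 0.36), and with hur scaling 1 fell (1 at an unadjusted p under 0.05). Of 18 tested miRNAs reported to respond to hypoxia, 3 rose and 6 fell (3 and 6 over the list alone, list adjusted p = 0.506), with a median of 0.02 that turned to -0.04 with cyclic loess and a downward test. Among the fallers was miR-210-3p, the best known target of hypoxia-inducible factor, which was 1.94-fold lower in normoxic EBs (1.70 to 2.22) but did not pass without scaling. In the Dlk1-Dio3 imprinted region on chromosome 12, where 22 of 22 tested members lie, 9 rose and 1 fell (5 and 1 over the list alone, list adjusted p = 0.0664). In the miR-17/92 list 9 of 24 rose and 0 fell (8 over the list alone, list adjusted p = 0.202), among them miR-92a-2-5p, which was detected on 1 of the 2 mESC arrays (adjusted p = 0.000643). Entries derived from ribosomal or transfer RNA, a sign of RNA fragments, rose in 2 of 5 cases (2 over the list alone, list adjusted p = 0.112), with a median log2 change of 0.47.

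In all, 248 of 484 tested miRNAs passed in this comparison, 126 higher and 122 lower in EBs, and 59 of them also differed at least 2-fold, 35 higher and 24 lower. The arrays of the 2 groups did not overlap for 79.3% of miRNAs, against 33.3% if all 4 arrays were exchangeable. If the arrays of a group repeat the same sample, any difference between samples would separate them. The excess therefore does not show a response to the condition. The split depended on scaling: it was 326 higher and 11 lower without any, 178 and 107 with median scaling, and 184 and 100 with scaling to the hur control features. The median of all tested miRNAs moved from 0.05 to 0.74 without scaling and to 0.15 with hur scaling, and directions here are relative to the bulk of miRNAs. With a floor 4 times as high let-7f-5p, let-7b-5p, miR-92a-2-5p, miR-199a-3p, miR-218-5p, miR-34a-3p and miR-34c-5p were at the floor and lost their calls, as did miR-124-5p, miR-669l-3p and miR-126-3p. Calls of miR-126-3p, miR-218-5p, miR-290-3p, miR-669e-3p and miR-669l-3p were also lost on leaving out 1 array or another, those of miR-126-3p and miR-218-5p with hur scaling, those of let-7b-5p and miR-218-5p without scaling, miR-34b-5p and miR-126-3p with quantile normalization, miR-126-3p with median scaling, miR-218-5p with a floor at 0.5 of the height, and miR-34c-5p with cyclic loess.

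The second comparison set EBs under hypoxia against EBs under normoxia. It shares its normoxic EB arrays with the first, so opposite changes in both are not independent results. miR-210-3p rose from 76.5 ± 3.99 to 176 ± 7.24, 2.31-fold (2.02 to 2.64, adjusted p = 0.00601), and was higher under every scaling tried. Of the 18 tested miRNAs reported to respond to hypoxia, 2 rose and 9 fell (2 and 9 over the list alone). The other riser was miR-125b-1-3p, detected on both hypoxic and neither normoxic EB array (adjusted p = 0.00601). Other entries of that miRNA were lower under hypoxia. The brighter miR-125b-5p had log2 changes over mESCs of 1.46 in normoxic and 1.16 in hypoxic EBs. miR-125b-2-3p read 13.1 and 17.6 unscaled units on normoxic and 9.79 and 8.45 on hypoxic EB arrays. The fallers past the threshold included miR-181c-5p and miR-26b-5p with log2 changes of -0.34 and -0.31. The list test was downward (adjusted p = 0.0253; adjusted p = 0.621 with an estimated correlation). With scaling to the hur features 0 members fell in the limma fit, 1 at an unadjusted p under 0.05. In the miR-34 family all 4 tested members fell (4 over the list alone), also with each of the other 6 scalings. miR-34b-5p went from 16.7 ± 1.40 to 7.57 ± 0.215, 2.20-fold lower (1.92 to 2.52), miR-34a-5p was 1.60-fold lower (1.41 to 1.82), and miR-34a-3p and miR-34c-5p were detected on both normoxic and neither hypoxic EB array (adjusted p = 0.00694 and 0.00611). The family passed (adjusted p = 0.00363; adjusted p = 0.459 with an estimated correlation), but not with a floor 4 times as high, where miR-34a-3p and miR-34c-5p were at the floor, or with no filter. Its median log2 change of -0.85 rests in part on these 2 members, set to the floor under hypoxia. Both were at the floor in mESCs too, so their rise in normoxic EBs and their fall here are the same normoxic readings.

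The proliferation-associated miR-17/92 cluster and its paralogues fell in 22 of 24 members (22 over the list alone), by a median of -0.36 in log2, with miR-19a-5p at -0.63 and miR-20a-3p at -0.51 (list adjusted p = 1.82e-08; adjusted p = 0.459 with an estimated correlation). Scaling to the hur features kept the median below 0, at -0.13, and left 6 members past the threshold. The miR-302/miR-367 cluster fell further in 6 of 7 members (6 over the list alone), with miR-302d-3p 1.33-fold lower (1.18 to 1.49; list adjusted p = 0.00462; adjusted p = 0.535 with an estimated correlation), though with hur scaling 0 members passed in the limma fit, also at an unadjusted p under 0.05, with a median of -0.17. Of the miR-290 to miR-295 cluster 7 members fell and 1 rose (6 and 1 over the list alone, list adjusted p = 0.0875), but the list median turned to 0.00 with hur scaling, where 5 members rose. The riser was miR-291b-5p, 2.06-fold (1.32 to 3.21), whose call was lost on leaving out any array but normoxic EB array 2, and miR-295-3p was 1.24-fold lower (1.09 to 1.42). Neural miRNAs fell in 5 of 8 cases (5 over the list alone), with miR-124-3p 1.29-fold lower (1.17 to 1.43; list adjusted p = 0.0253; adjusted p = 0.534 with an estimated correlation). With hur scaling 0 of them passed in the limma fit, 2 at an unadjusted p under 0.05. Without hypoxic EB array 2 the neural, hypoxia and fibroblast lists did not pass, nor did the neural list without normoxic EB array 1.

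**Figure D2:**
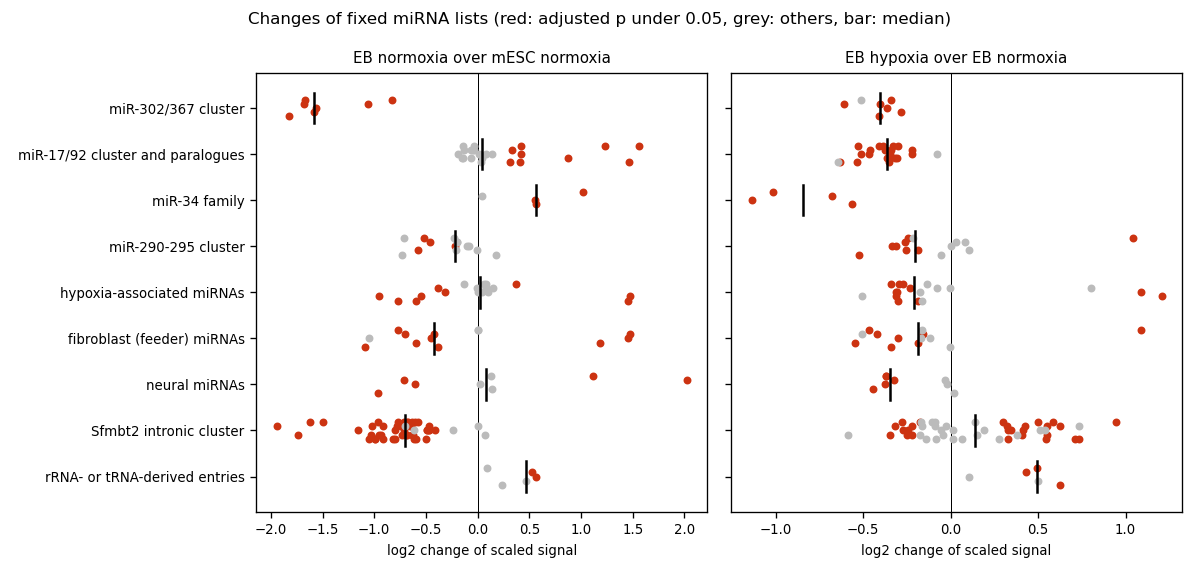
Log2 change of scaled signal of each tested member of 9 fixed lists, for normoxic EBs over mESCs (left) and hypoxic over normoxic EBs (right), with members past an adjusted p of 0.05 in red and list medians as bars. The miR-302/miR-367 median lies at -1.59 and -0.40 and the miR-34 median at 0.56 and -0.85, while the miR-290 to miR-295 median of -0.22 turns to 0.51 without scaling and its -0.20 turns to 0.00 with hur scaling. Both panels share the normoxic EB arrays, and miR-34a-3p and miR-34c-5p were at the floor in mESCs and in hypoxic EBs.

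In the Sfmbt2 cluster 17 of 49 members rose and 9 fell under hypoxia (16 and 9 over the list alone, list adjusted p = 0.768), but with hur scaling 22 rose and 0 fell (26 and 0 at an unadjusted p under 0.05). Its median of 0.14 turned to -0.09 without scaling. Among the risers was miR-466h-3p with a log2 change of 0.71. In the Dlk1-Dio3 region 7 rose and 4 fell (7 and 4 over the list alone, list adjusted p = 0.768), with a median of -0.12 that turned to 0.03 with hur scaling. Among them miR-370-3p rose 1.74-fold (1.52 to 2.00), miR-493-3p was detected on both hypoxic and neither normoxic EB array (adjusted p = 0.00694), and miR-434-3p the other way round (adjusted p = 0.00705). For that list the camera test was downward, while the mean was 0.00 and the fry test upward. Fibroblast miRNAs fell in 7 of 13 cases and rose in 1 (7 and 1 over the list alone, list adjusted p = 0.0253; adjusted p = 0.459 with an estimated correlation), with miR-22-3p at -0.47 in log2 and a median that turned to 0.05 with hur scaling, where 1 rose and 1 fell (2 and 1 at an unadjusted p under 0.05). This list shares 6 tested members with the hypoxia list. In the miR-200 family 1 of 6 fell (0 over the list alone, list adjusted p = 0.346), with a median of -0.11 that turned to 0.13 with hur scaling. Of 4 blood-cell miRNAs miR-155-5p rose and miR-142-3p fell (1 and 1 over the list alone, list adjusted p = 0.481), and 0 of 6 let-7 members passed in the limma fit (0 over the list alone and 0 at an unadjusted p under 0.05, list adjusted p = 0.768), with a median of 0.00 that was -0.16 without scaling and 0.12 with hur scaling. miR-208a-5p had a log2 change of 0.25 and passed only over its list, in which it is the 1 tested member, and miR-126-3p had -0.15, which turned to 0.09 with hur scaling. Entries derived from ribosomal or transfer RNA rose in 3 of 5 cases (3 over the list alone, list adjusted p = 0.107), by 0.62 in log2 for miR-6240. Outside the lists, miR-711 rose 2.61-fold (1.97 to 3.46), miR-3473c was detected on both hypoxic and neither normoxic EB array (adjusted p = 0.00908), and miR-6415 was 2.68-fold lower (1.39 to 5.18), a call lost on leaving out any of the 4 EB arrays. With a floor 4 times as high miR-711, miR-3473c, miR-493-3p, miR-434-3p, miR-125b-1-3p, miR-19a-5p, miR-291b-5p and miR-6415 lost their calls. With hur scaling miR-124-3p, miR-142-3p, miR-181c-5p, miR-26b-5p, miR-295-3p and miR-302d-3p lost theirs, without scaling miR-155-5p, miR-26b-5p, miR-291b-5p and miR-466h-3p, and with quantile normalization miR-295-3p, miR-3473c and miR-6415. Leaving out 1 array or another also ended those of miR-155-5p, miR-26b-5p, miR-295-3p and miR-466h-3p.

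In all, 281 of 484 miRNAs passed between the EB groups, 159 higher and 122 lower under hypoxia, but only 13 also differed at least 2-fold, 10 higher and 3 lower. Arrays did not overlap for 84.7% of miRNAs, against 33.3% for exchangeable arrays, an excess that repeats of the same sample could also give. The split was 24 higher and 115 lower without scaling, 231 and 15 with hur scaling, 116 and 140 with quantile normalization, and 134 and 158 with cyclic loess. The median of all tested miRNAs was 0.10, against -0.10 without scaling, 0.34 with hur scaling and 0.00 with quantile normalization.

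The third comparison set hypoxic EBs against mESCs and shares its arrays with the other two. It spans both changes of condition, so that cell state and oxygen differ together. The miR-302/miR-367 cluster was lower again, with all 7 members down (7 over the list alone) and miR-302d-3p 4.72-fold lower (4.20 to 5.30; list adjusted p = 0.000234; adjusted p = 0.407 with an estimated correlation). The Sfmbt2 cluster fell in 34 of 49 members and rose in 1 (33 and 1 over the list alone; list adjusted p = 1.21e-09; adjusted p = 0.309 with an estimated correlation), while without scaling 6 fell and 2 rose. Of miR-290 to miR-295, 12 of 14 members fell (12 over the list alone), with miR-294-3p 1.39-fold lower (1.21 to 1.60; list adjusted p = 0.00231; adjusted p = 0.407 with an estimated correlation). That direction turned without scaling (median 0.07), and with hur scaling 1 member rose and 1 fell (2 and 2 at an unadjusted p under 0.05). The call of miR-294-3p was lost there and with quantile normalization. The miR-17/92 list had 14 members down and 3 up of 24 (14 and 3 over the list alone; list adjusted p = 0.0389; adjusted p = 0.522 with an estimated correlation), and its median of -0.32 turned to 0.12 without scaling and 0.01 with hur scaling, where 9 rose and 1 fell (9 and 2 at an unadjusted p under 0.05). It did not pass with median scaling, a floor at 0.5 of the height or no filter either.

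All 5 entries derived from ribosomal or transfer RNA rose in this comparison (5 over the list alone, list adjusted p = 0.0565), by 0.96 in log2 for miR-5109, whose call was lost with quantile normalization. All 4 blood-cell miRNAs rose (4 over the list alone, list adjusted p = 0.0565), with miR-150-5p up 2.50-fold (2.25 to 2.79). miR-210-3p was 1.19-fold higher than in mESCs (1.04 to 1.36, adjusted p = 0.031), a call lost on leaving out any mESC or hypoxic EB array with quantile normalization and with scaling to all mouse miRNAs. Fibroblast miRNAs fell in 9 of 13 cases and rose in 3 (9 and 3 over the list alone, list adjusted p = 0.0565), with miR-21a-5p 2.69-fold lower (2.33 to 3.11), while with hur scaling 5 fell and 3 rose (5 and 4 at an unadjusted p under 0.05). Hypoxia-associated miRNAs fell in 9 and rose in 3 of 18 cases (9 and 3 over the list alone, list adjusted p = 0.136), with a median of -0.21 that turned to 0.27 without scaling and 0.11 with hur scaling, where 4 rose and 3 fell (6 and 4 at an unadjusted p under 0.05). Of the Dlk1-Dio3 region 10 rose and 3 fell (8 and 3 over the list alone, list adjusted p = 0.214), its median turning to -0.10 with cyclic loess. The neural list had 2 up and 6 down of 8 (2 and 6 over the list alone, list adjusted p = 0.241), with miR-124-3p 1.68-fold higher (1.52 to 1.86) and a median that turned to 0.17 without scaling and 0.01 with hur scaling (2 up and 1 down there, 2 and 1 at an unadjusted p under 0.05), while fry was upward and camera downward. In the miR-200 family 5 of 6 fell (5 over the list alone, list adjusted p = 0.0577), turning without scaling (median 0.03), and with hur scaling 0 fell (0 at an unadjusted p under 0.05). In the miR-34 family 2 of 4 fell (2 over the list alone, list adjusted p = 0.214). The others, miR-34a-3p and miR-34c-5p, were detected on no array of either group and sat at the floor in both. In the let-7 family 2 of 6 rose and 1 fell (2 and 1 over the list alone, list adjusted p = 0.931), with a median of -0.04 that turned to 0.23 without scaling and 0.17 with hur scaling. miR-208a-5p, whose other arm was detected on no array, rose 2.35-fold (2.01 to 2.76). miR-126-3p fell by 0.50 in log2, a call lost without scaling and with hur scaling.

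Of the 484 tested miRNAs 363 passed, 200 higher and 163 lower in hypoxic EBs, and 77 of them also differed at least 2-fold, 59 higher and 18 lower. Detection was lopsided: 56 miRNAs were detected on both hypoxic EB arrays and neither mESC array, and 1, miR-224-5p, the other way round (adjusted p = 0.000244; at the floor and not past the threshold with a floor 4 times as high). The flags precede scaling and the mESC arrays were dimmer than the EB arrays, so brightness alone can shift this count. The 56 include miR-6388 (adjusted p = 0.000244), and miR-598-5p, detected in both groups, was 3.55-fold higher (2.96 to 4.26). Arrays did not overlap for 88% of miRNAs, against 33.3% for exchangeable arrays, with the same limit. Without scaling the split was 251 higher and 19 lower, and with hur scaling 251 and 60. The median of all tested miRNAs was 0.11, against 0.57 without scaling, 0.44 with hur scaling, 0.00 with quantile normalization and -0.07 with cyclic loess.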

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

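The tests of explanations in this part were all chosen after the results had been seen. Control features named hur, which belong to no comparison, were brighter on EB than on mESC arrays before scaling. Their mean log2 difference was 0.62 ± 0.135 (SD over 5 features) for normoxic EBs over mESCs, beside a median of 0.73 for the mouse miRNAs. For hypoxic EBs over mESCs it was 0.157 ± 0.05, beside 0.42 for the mouse miRNAs. For hypoxic over normoxic EBs it was -0.467 ± 0.1, beside -0.145. Other detected control features did not all follow hur there. Before scaling mr_1 read 4943 and 5196 on normoxic and 4655 and 4496 on hypoxic EB arrays. The feature miRNABrightCorner30 read 2256 and 2941 on normoxic and 4111 and 2433 on hypoxic EB arrays.

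Under hypoxia, entries numbered 1000 or above rose relative to lower-numbered entries, with median log2 changes of 0.42 (154 entries, 83 rose and 7 fell) and -0.13 (330 entries, 76 rose and 115 fell). In normoxic EBs against mESCs, both labelled normoxia, the same class was also above, at 0.23 (48 rose and 14 fell) and -0.03 (78 rose and 108 fell). A signal-dependent response of the array is argued against: the class difference averaged over 10 bins of signal was 0.56, and the difference of 0.55 lay outside the central 95% of 10000 permutations within those bins (-0.14 to 0.20). Fragments of abundant RNA stay open, since the 5 entries derived from rRNA or tRNA lay 0.62 above the lower-numbered entries, and 0.53 to 0.65 above them over 6 scalings. All 5 belong to the class that rose, so that test is not independent of the pattern. An effect of hypoxia, the condition the design names, stays open as untested. Between normoxic EBs and mESCs the labelled oxygen condition did not differ, but oxygen within the EBs was not tested.

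The 7 fibroblast-list miRNAs that fell from mESCs to normoxic EBs had a median log2 change of -0.60. RNA of feeder fibroblasts as the whole cause is weakly argued against: of 9 probes for miR-143, miR-145a, miR-199a, miR-199b and miR-214, abundant in mesenchymal cells, 0 were detected on both mESC arrays, whereas 1, miR-199a-3p, was detected on both normoxic EB arrays, grown without feeders. Most of the other probes were detected on no array at all. No fibroblast sample shows that they would detect feeder RNA, so the argument rests mainly on miR-199a-3p. The fall did not hinge on which scaling between arrays was used: the median was -0.49 with hur scaling (SD 0.249, 6 of the 7 fell), -0.61 with the 75th percentile of all (7 fell), -0.51 with median scaling (6 fell) and -0.50 with quantile normalization (6 fell). The 7 were picked as fallers under the main scaling of the same arrays, so this cannot exclude scaling as a cause. Leaving scaling out, which was tried first, put the median at 0.13 with 2 of the 7 lower and decides nothing, since it moved the median of all tested miRNAs from 0.05 to 0.74. Every scaling takes some signal as constant and what the hur features are is not known, so a change in total miRNA stays open, as does the difference between mESCs and EBs that the design names, which was not tested.

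Minor arms of the miR-17/92 list, the dimmer entries of each hairpin name, rose in normoxic EBs in 9 of 12 cases (median log2 change 0.41), while 0 of 12 major arms rose or fell (median -0.07). Among the minor arms, miR-19b-1-5p, miR-363-5p and miR-93-3p were detected on neither mESC array. Detection of miR-92a-1-5p and miR-92a-2-5p was on 1 mESC array, so the changes of these 5 depend on the floor. Scaling is argued against: within 7 hairpins with both arms detected on all arrays, the unscaled change of minor over major arm had a median of 0.35 (SD 0.16) and was above 0 in 7. A signal-dependent response stays open, since the minor arms' median was at percentile 96.2 of 10000 sets of other miRNAs of the same signal, inside the central 95% (-0.26 to 0.45). A looser one-sided limit at the 95th percentile (0.38), which was tried first, would have put it outside. In 60 other hairpins the minor arm was up on the major in 33, and the difference between mESCs and EBs that the design names stays open as untested.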

How the results depend on the processing

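Scaling to the hur features and cyclic loess were chosen after the data had been seen. Of the named miRNAs, 45 of 57 for normoxic EBs against mESCs, 51 of 52 for hypoxic against normoxic EBs and 57 of 63 for hypoxic EBs against mESCs reversed under no alternative, and 12, 4 and 21 also kept their side of the threshold under every alternative. miR-210-3p was higher under hypoxia by 0.97 to 1.44 in log2 over all alternatives. Over all named miRNAs and alternatives, a call was lost in 574 cases and gained in 3. The cause of the changes below was not tested unless stated. The labels do not say that array numbers pair. Deviations of same-numbered arrays correlated at 0.02, 0.06 and -0.02, which cannot exclude pairing, since arrays of a group differed by less than the scanner's error. With the replicate block 242, 263 and 357 miRNAs and 3, 6 and 4 lists passed. The small number of arrays and signals near the floor limit the precision.

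Counts of miRNAs in the 3 comparisons in that order were 248, 281 and 363. They became 62, 20 and 82 when at least 2-fold without overlap was asked, and 94, 20 and 231 with no filter, where undetected miRNAs enter the fit. For normoxic EBs against mESCs a floor 4 times as high gave 154. For hypoxic against normoxic EBs no scaling gave 139 and the authors' normalized values 46. Leaving out each array in turn gave 142 (without mESC array 1) to 258, 160 (without normoxic EB array 1; 173 without hypoxic EB array 2) to 264, and 283 to 355.

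Lists past the threshold were 3, 6 and 4. They were 0, 0 and 0 with an estimated correlation. fry, which asks whether a list moves rather than whether it stands apart, gave 11 for normoxic EBs and 11 for hypoxic EBs against mESCs. For normoxic EBs against mESCs no filter gave 5, for hypoxic against normoxic EBs no scaling gave 3, and for hypoxic EBs against mESCs a floor 4 times as high gave 8 and cyclic loess 7. Leaving out each array gave 3 to 5 (5 without normoxic EB array 2), 3 (without hypoxic EB array 2) to 7, and 4 to 7 (7 without hypoxic EB array 1).

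Without scaling, and equally with the authors' normalized values, which have none, named miRNAs that had been lower in normoxic EBs than in mESCs became higher: miR-126-3p 0.38, miR-200a-3p 0.43, miR-200b-3p 0.41, miR-200c-3p 0.24, miR-290-3p 0.21, miR-291a-5p 0.16, miR-292-5p 0.51, miR-294-3p 0.50, miR-294-5p 0.27, miR-295-3p 0.63, miR-429-3p 0.31 and miR-9-3p 0.021. For hypoxic EBs against mESCs the same held for miR-200b-3p 0.026, miR-200c-3p 0.038, miR-293-3p 0.026, miR-294-3p 0.023 and miR-295-3p 0.083. With hur scaling miR-295-3p turned to 0.002 for normoxic EBs against mESCs and miR-200a-3p to 0.011 for hypoxic against normoxic EBs. With quantile normalization let-7a-5p turned to -0.071 for hypoxic EBs against mESCs.

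Lists whose test turned direction did not pass in the main analysis. Values are the mean log2 change of the list minus that of the other miRNAs, whose sign can differ from that of the test; with fry they are the plain mean log2 change. For the let-7 family in normoxic EBs against mESCs the value was -0.001 in the main analysis, with only the 4 arrays compared and with the replicate block, 0.58 with the authors' values, -0.26 with cyclic loess, -0.21 for miRNAs detected on all 6 arrays, -0.024 with median scaling, -0.005 with no filter, -0.14 without scaling, -0.29 with quantile normalization, -0.027 with hur scaling, and -0.11 to 0.11 leaving out each array. For let-7 in hypoxic against normoxic EBs it was 0.55 with the authors' values, 0.11 for miRNAs detected on all 6 arrays, -0.012 with a floor at 0.5 of the height, -0.005 with no filter, and -0.16 to 0.05 leaving out each array. For let-7 in hypoxic EBs against mESCs it was -0.43 with cyclic loess, -0.10 for miRNAs detected on all 6 arrays, -0.084 with median scaling, -0.011 with no filter, -0.19 without scaling, -0.43 with quantile normalization, -0.14 with hur scaling, and -0.12 to 0.002 leaving out each array.

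For the Dlk1-Dio3 list in hypoxic against normoxic EBs the value was -0.97 with the authors' values, 0.13 for miRNAs detected on all 6 arrays, -0.005 with a floor 4 times as high, 0.004 (plain mean) with fry, -0.054 with no filter, and -0.23 to -0.01 leaving out each array. In hypoxic EBs against mESCs it was 0.024 with no filter. For the Sfmbt2 list in hypoxic against normoxic EBs it was 0.043 with a floor 4 times as high, 0.077 with no filter, and -0.026 to 0.10 leaving out each array. For entries derived from rRNA or tRNA it was 0.38 with no filter in that comparison. The neural list turned with fry in hypoxic EBs against mESCs (plain mean -0.10) and without scaling in normoxic EBs against mESCs (0.12).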

Other observations

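These groups of neighbouring miRNAs and the splits named here were picked after their values had been seen. The miR-183/96/182 cluster on chromosome 6, expressed in sensory organs and in ES cells, rose in normoxic EBs over mESCs in 4 of 4 tested members, with a median log2 change of 0.44 (0.31 to 0.58). Under hypoxia 3 of the 4 fell, with a median of -0.27, but with hur scaling 0 fell (0 at an unadjusted p under 0.05) and the median was -0.03. The miR-130b/301b cluster on chromosome 16 fell under hypoxia in 3 of 3 tested members, with a median of -0.33 (-0.51 to -0.30), after 1 of 3 had risen in normoxic EBs. With hur scaling 0 of them fell under hypoxia (1 at an unadjusted p under 0.05), with a median of -0.09.

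Other neighbours did not move together. In the miR-99b/125a cluster on chromosome 17, 2 of 4 tested members rose and 2 fell under hypoxia, with log2 changes from -0.29 to 0.57 (2 rose and 0 fell with hur scaling). In the cluster of miR-500, miR-362, miR-188 and miR-532 on chromosome X, 2 rose and 1 fell, from -0.80 to 0.54 (2 rose and 0 fell with hur scaling).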
